A study of Drosophila melanogaster with 9 samples.

How the data were processed

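RNA from dissected Drosophila melanogaster brains was measured on 9 Affymetrix Drosophila 2.0 arrays, 3 each at 3, 30 and 60 days of age. Per the labels, flies aged naturally, RNA was extracted with Trizol, and the target was amplified and biotin labelled with the FL-Ovation cDNA Biotin Module. The deposited table gives each of 18952 probe sets a linear signal intensity per array. The submitters' processing notes name GCRMA and MAS5 without saying what each did and without a version. The values are of the MAS5 kind, linear and scaled so that the trimmed mean of every array was 150.002, and they were not quantile normalized. The median signal per array ran from 60.7 to 78.3, and the number of arrays limits the precision.

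Values were analysed as log2(signal + 1), because the table was linear, with no further normalization between arrays. The 183 control probe sets were left out of the gene comparisons. Names came from the platform's annotation and a gene reference table, with no genome used. Of the probe sets 13647 had 1 gene, 402 several and 4720 none named, and the entrez identifier of 13544 was in the reference table. For each of the 11982 genes with a probe set of its own, the probe set with the highest mean over all arrays was taken. This choice concerned 1094 genes that had more than 1 probe set. Genes stayed in if at least 3 arrays exceeded the 40th percentile of all values (5.71 on the log2 scale), which left 8171. The ecdysone-induced gene Eip74EF has no probe set of its own in the annotation and was not analysed here.

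Changes were tested with limma 3.58.1 in R 4.3.3, with group means for the 3 ages fitted to all 9 arrays, 6 residual degrees of freedom and an empirical Bayes prior of 5.51 degrees of freedom. Comparisons were 60d against 3d, 30d against 3d, 60d against 30d, the difference between the intervals (the change from 30 to 60 days minus that from 3 to 30 days) and an F-test over the 3 ages. Tests were two-sided, and Benjamini-Hochberg adjustment covered all genes tested, with a threshold of 0.05. Whether a gene list moved against the other genes was tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over 31 lists. Beside it camera was run with an estimated correlation, and fry, which asks whether a list's genes move one way on balance. The median of each list was also set against those of 10000 random lists of genes of the same signal levels. The text says where the median of a called list lay within their middle 95%, and where that of a list not called lay outside it. Differences in RNA quality between ages were tested by exact permutation over all 1680 arrangements of the arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

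The lists, the comparisons, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The lists covered immunity, stress, metabolism, neuronal function and markers of other cell types, and 1044 of their members matched the annotation while 161 did not. Many marker genes are also present in brain: the 3d mean exceeded the 60th percentile of all values (6.67) for 14 of 21 head fat body markers, 8 of 14 haemocyte markers, 12 of 20 muscle markers, 24 of 27 retina genes, 2 of 7 olfactory appendage markers, 21 of 48 cuticle proteins, 20 of 21 glia markers, 2 of 5 gut markers and 9 of 14 sex-biased transcripts. Another list also held 6 of the fat body markers, 5 of the sex-biased transcripts, 1 of the retina genes and 1 of the cuticle proteins.

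Named genes were the 12 largest rises and 12 largest falls between 3d and 60d, and the 8 largest of each in the other pairwise comparisons. They had to pass the test, have no overlap between the arrays of the 2 ages, which chance gives for 10% of genes, and have a mean above the 60th percentile in the higher group. For each list up to 3 called members in each direction were named for 60d against 3d and up to 2 otherwise, or the member with the smallest p where none passed. For the difference between intervals, 6 genes in each direction were named under the same level and test conditions. From these the text names a part, and the values of list members on single arrays were added after the comparisons had been seen.

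The procedure was tested on simulated data of the same size, 10 draws with 200 changed genes each in the 60d against 3d comparison. It recovered 93.1% of 2-fold and 100% of 4-fold changes, 4.55% of its calls were false and 0 had the wrong sign. In the unchanged 30d against 3d comparison it made 0 calls. A list shifted by -0.5 was called in 10 of 10 draws. Each simulated gene had the same SD at every age, and genes varied independently of each other. The real arrays differ in spread between ages and real genes vary together, so these rates need not hold for them.

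Alternatives covered quantile normalization, median centring, no filter, a stricter filter at the 60th percentile, a floor for low values, every probe set as its own unit, the mean of a gene's probe sets, a pseudocount of 16, an intensity trend with robust prior, array weights, a replicate block, each array left out, only the 6 arrays of the ages compared, and a 2-fold minimum. For lists they covered camera with estimated correlation, camera on ranks and fry. Added after seeing the data were cyclic loess between arrays, the 3' to 5' control ratio of each array as a covariate, leaving out the first arrays of 3d and 60d together, and the pseudocount of 16 for lists.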

Results

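Gene expression was measured in dissected Drosophila melanogaster brains on 9 Affymetrix Drosophila 2.0 arrays, 3 arrays each from flies aged 3, 30 and 60 days (3d, 30d and 60d). Pairwise comparisons of the ages ask which brain transcripts differ between young, middle-aged and old flies, and over which interval. The labels do not say whether the replicates of an age were separate animals or pools, so the p-values measure only the spread between these arrays. The median signal was 65.1, 67.6 and 60.7 on 3d replicates 1, 2 and 3. It was 76.1, 78.3 and 77.7 on those of 30d, and 66.5, 77.0 and 74.3 on those of 60d. Every 30d array thus had a higher median signal than every 3d array, so this difference goes with age in that comparison. The number of arrays limits the precision. Gene levels are given as mean log2(signal + 1) ± SD with n = 3 arrays per age, and changes as log2 differences ± SE from limma.

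Replicates differed more at 3d and 60d than at 30d. The median within-age SD of a gene was 0.229 at 3d, 0.094 at 30d and 0.209 at 60d. The first principal component held 53.2% of the variance. On it the 3d arrays lay between -37.1 and -20.9 and the 30d arrays between 18.1 and 22.8, whereas 60d replicates 1, 2 and 3 lay at -11.6, 21.7 and 7.1. The RNA quality control for GAPDH had a log2 ratio of 3' to 5' signal of 5.03 on 3d replicate 1 and of 1.58 to 2.07 on the other arrays. Across 7 such control ratios the exact permutation p of an F statistic over the 3 ages ran from 0.0821 to 0.954, with a lowest adjusted p of 0.575. That test compares ages and cannot show 1 outlying array. For the GAPDH ratio the SD was 1.88 at 3d, 0.05 at 30d and 0.08 at 60d.

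Old brains carried far more of several immune and stress-response transcripts than young brains. TotC, a secreted stress-induced protein, rose from 5.46 ± 0.68 at 3d to 11.22 ± 0.31 at 60d, a 54.3-fold rise (adjusted p = 1.95e-06). Its 3d mean lay below the filter value of 5.71, so the size of the fold rise rests on a dim signal. DptB, Mtk and Drs, which encode antimicrobial peptides, rose by 3.86 ± 0.51, 2.88 ± 0.41 and 1.14 ± 0.19 (adjusted p = 0.0011, 0.00163 and 0.00288). PGRP-SB1, a secreted peptidoglycan-degrading enzyme, rose by 3.56 ± 0.42, and the virus-induced transcript vir-1 by 1.53 ± 0.21 (adjusted p = 0.000607 and 0.00153). Diedel, a secreted immune regulator, rose by 2.85 ± 0.32 (adjusted p = 0.00052). Of 9 measured antimicrobial peptide genes 4 rose and 5 did not pass, and 6 rose when adjusted over the list alone. The list was called up by camera (adjusted p = 0.000251, and adjusted p = 0.213 with an estimated correlation). Of 34 immune recognition and signalling genes 12 rose, 1 fell and 21 did not pass, or 13 and 1 adjusted over the list alone (camera adjusted p = 7.3e-06, and adjusted p = 0.213 with an estimated correlation). Relative to the 3d mean, the median immune recognition gene stood at 0.46, 0.42 and 0.41 on 60d replicates 1, 2 and 3, and the median antimicrobial peptide gene at 0.75, 0.88 and 0.68. The median head fat body marker stood at 0.70, -0.31 and 0.51 on the same arrays.

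**Figure D1:**
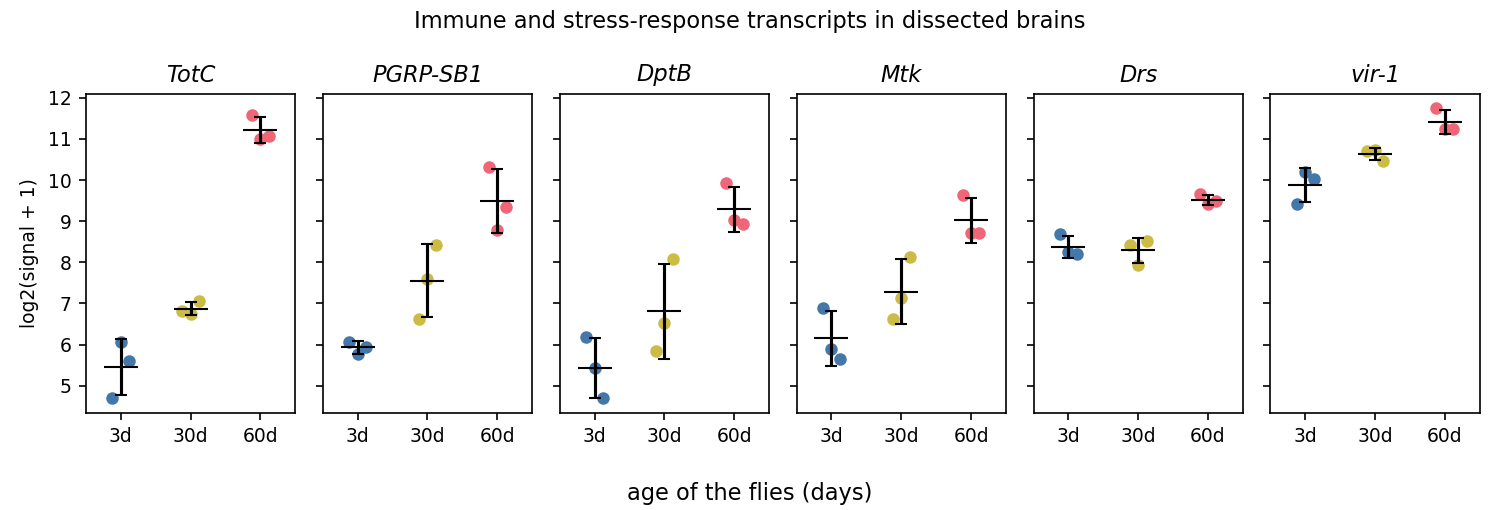
Signal of 6 immune and stress-response genes, as log2(signal + 1) on the vertical axis against age in days, with 1 point per array and bars for the mean ± SD of 3 arrays. TotC rises from a mean of 5.46 at 3d through 6.87 at 30d to 11.22 at 60d, and Drs from 8.29 at 30d to 9.52 at 60d.

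Some detoxification enzymes and several transcripts of other kinds also rose between 3d and 60d, although most P450 and antioxidant genes did not pass. Gnmt, a methyltransferase that consumes S-adenosylmethionine, rose by 3.58 ± 0.38, and the tetraspanin Tsp42Ed by 3.27 ± 0.18 (adjusted p = 0.000427 and 4e-06). The serpin Spn88Eb rose by 2.40 ± 0.22, the transporter MFS3 by 2.24 ± 0.18 and Arc2, a capsid-forming homologue of a neuronal plasticity gene, by 2.12 ± 0.20 (adjusted p = 0.000188, 0.0001 and 0.000188). Of 45 cytochrome P450 genes 12 rose, 2 fell and 31 did not pass, or 16 and 2 adjusted over the list alone. Among them Cyp6g1 and Cyp6a23 rose by 1.80 ± 0.23 and 1.30 ± 0.26 (adjusted p = 0.000932 and 0.00704). The P450 list was called up (camera adjusted p = 0.0092, and adjusted p = 0.296 with an estimated correlation), but not with the first arrays of 3d and 60d left out together (adjusted p = 0.121). Of 44 antioxidant and glutathione genes 8 rose, 2 fell and 34 did not pass, or 11 and 4 adjusted over the list alone. The glutathione transferases GstT4 and GstD2 rose by 1.98 ± 0.28 and 1.34 ± 0.16, and the mitochondrial superoxide dismutase Sod2 fell by 0.98 ± 0.14 (adjusted p = 0.00156, 0.000684 and 0.00161). That list was called up (camera adjusted p = 0.0234, and adjusted p = 0.431 with an estimated correlation). Its call was lost without 3d replicate 1 (adjusted p = 0.0782), without 60d replicate 1 (adjusted p = 0.145), without both (adjusted p = 0.354) or with the 3' to 5' ratio as a covariate (adjusted p = 0.0675). Of 28 heat shock proteins and chaperones 6 rose, 2 fell and 20 did not pass, or 11 and 4 adjusted over the list alone. CCT5, Hsp68 and Hsp26 rose by 1.32 ± 0.20, 1.14 ± 0.14 and 0.99 ± 0.15 (adjusted p = 0.0021, 0.000607 and 0.00221), while the list itself was not called (camera adjusted p = 0.157). Hsp22, Hsp23, Hsp83 and the Hsp70 genes of this list did not match the annotation and were not tested.

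Many transcripts for mitochondrial energy metabolism were lower in old brains. Of 67 genes of the electron transport chain and ATP synthase 42 fell, 1 rose and 24 did not pass, or 51 and 3 adjusted over the list alone, and their median change was -0.64 (camera adjusted p = 4.41e-15, and adjusted p = 0.213 with an estimated correlation). ND-75, a subunit of complex I, fell from 8.86 ± 0.54 at 3d to 7.49 ± 0.28 at 60d, a change of -1.36 ± 0.24 (adjusted p = 0.00413). The ATP synthase subunits ATPsyngamma and ATPsynB fell by 1.20 ± 0.18 and 1.13 ± 0.17 (adjusted p = 0.00218 and 0.00213). Of 11 genes of the tricarboxylic acid cycle 4 fell and 7 did not pass, with 4 also adjusted over the list alone (camera adjusted p = 0.00324, and adjusted p = 0.414 with an estimated correlation). The aconitase mAcon1 and the isocitrate dehydrogenase subunit Idh3g fell by 1.08 ± 0.16 and 1.07 ± 0.14 (adjusted p = 0.00213 and 0.00116). Of 69 mitochondrial ribosomal proteins 16 fell and 53 did not pass, with 16 also adjusted over the list alone (camera adjusted p = 5.76e-08, and adjusted p = 0.414 with an estimated correlation). They included mRpS30 at -0.71 ± 0.15 and mRpL51 at -0.69 ± 0.14 (adjusted p = 0.00932 and 0.00771). Of 10 glycolysis genes 3 fell and 7 did not pass, or 4 adjusted over the list alone, among them Pgk at -1.05 ± 0.20 and Gapdh1 at -0.97 ± 0.19 (adjusted p = 0.0053 and 0.00676). The glycolysis list was called down (camera adjusted p = 0.0254, and adjusted p = 0.514 with an estimated correlation), but not without 3d replicate 3 (adjusted p = 0.0601) or 60d replicate 2 (adjusted p = 0.0854), nor with quantile normalization (adjusted p = 0.256), cyclic loess (adjusted p = 0.134), the stricter filter (adjusted p = 0.0675) or fry (adjusted p = 0.0763). Against random lists of the same signal levels, the medians of the tricarboxylic acid cycle (-0.26) and glycolysis (-0.35) lists lay within the middle 95% (-0.35 to 0.19 and -0.35 to 0.18), glycolysis at its edge (percentile 2.57), and those of the electron transport and mitochondrial ribosomal lists at percentile 0. Relative to the 3d mean, 60d replicates 1, 2 and 3 stood at -0.43, -0.82 and -0.67 for the median electron transport gene, at -0.11, -0.77 and -0.37 for the tricarboxylic acid cycle and at -0.04, -0.53 and -0.38 for glycolysis. On the first principal component these arrays lay at -11.6, 21.7 and 7.1.

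Some synaptic and receptor transcripts fell between 3d and 60d. Of 28 synaptic vesicle and active zone genes 11 fell and 17 did not pass, or 15 adjusted over the list alone (camera adjusted p = 3.49e-06, and adjusted p = 0.213 with an estimated correlation). Rop, a regulator of vesicle fusion, fell by 1.10 ± 0.20, the calcium sensor Syt7 by 0.90 ± 0.14 and alphaSnap, which helps recycle fusion complexes, by 0.85 ± 0.14 (adjusted p = 0.00494, 0.0021 and 0.00317). Of 29 neurotransmitter receptors 8 fell and 21 did not pass, or 10 adjusted over the list alone (camera adjusted p = 0.00643, and adjusted p = 0.213 with an estimated correlation). The receptor median of -0.18 lay within the middle 95% of random lists of the same signal levels (-0.20 to 0.16). The nicotinic receptor subunits nAChRbeta1 and nAChRbeta2 fell by 0.84 ± 0.15 and 0.65 ± 0.13 (adjusted p = 0.00472 and 0.00748). Of 23 voltage-gated and related ion channels 6 fell and 17 did not pass, with 6 also adjusted over the list alone, and the list was not called (camera adjusted p = 0.0554), although fry called it down (adjusted p = 0.0301). Of 31 neuropeptide and peptide hormone genes 2 rose, 5 fell and 24 did not pass, the same counts as adjusted over the list alone. Among them the insulin-like peptide Ilp5 fell by 1.38 ± 0.22 and SIFa by 1.20 ± 0.15 (adjusted p = 0.00278 and 0.00076). The neuropeptide list was not called (camera adjusted p = 0.681), with a median of 0.08, a mean of -0.04 and a test directed down. Of 21 glia markers 2 rose, 4 fell and 15 did not pass, or 3 and 5 adjusted over the list alone (camera adjusted p = 0.173). The septate junction gene Gli rose by 1.32 ± 0.19, and e (ebony), which conjugates amines in glia, fell by 1.53 ± 0.20 (adjusted p = 0.00187 and 0.000932). Single genes with large falls also included Gycalpha99B, a subunit of soluble guanylyl cyclase, at -1.60 ± 0.15 and the lipid phosphatase wun2 at -1.99 ± 0.16 (adjusted p = 0.000188 and 0.000108).

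Eye markers were called down as a list, and the lists of muscle, olfactory appendage and cuticle genes were called up, although most muscle and cuticle members did not pass. Of 27 phototransduction and retina genes 14 fell and 13 did not pass, with 14 also adjusted over the list alone (camera adjusted p = 1.87e-06, and adjusted p = 0.213 with an estimated correlation). The list members ninaE, Rh2, Rh3, Rh4, Rh5, Rh6 and norpA did not match the annotation and were not tested. The lens protein retinin fell by 1.86 ± 0.18, the light-activated channel trpl by 1.59 ± 0.24 and boss, a photoreceptor ligand, by 1.26 ± 0.14 (adjusted p = 0.000188, 0.00198 and 0.000512). Of 20 muscle markers 5 rose and 15 did not pass, with 5 also adjusted over the list alone (camera adjusted p = 0.000653, and adjusted p = 0.213 with an estimated correlation). Mp20, Mlp60A and the giant muscle protein bt rose by 1.92 ± 0.28, 1.56 ± 0.20 and 1.47 ± 0.16 (adjusted p = 0.00193, 0.001 and 0.000478). Of 7 olfactory appendage markers 3 rose and 4 did not pass, or 5 adjusted over the list alone (camera adjusted p = 0.00643, and adjusted p = 0.213 with an estimated correlation). The odorant-binding protein Obp19d rose by 1.89 ± 0.23 (adjusted p = 0.000686), and the list was not called with quantile normalization (adjusted p = 0.0525). Of 48 cuticle proteins 3 rose, 1 fell and 44 did not pass, or 1 and 1 adjusted over the list alone, with TwdlE at 0.80 ± 0.13 and Cpr49Ag at -2.07 ± 0.31 (adjusted p = 0.00315 and 0.00201). The cuticle list was called up (camera adjusted p = 0.0107, and adjusted p = 0.627 with an estimated correlation), but not without 3d replicate 3 (adjusted p = 0.263) or 60d replicate 2 (adjusted p = 0.225), nor with cyclic loess (adjusted p = 0.0583) or fry (adjusted p = 0.27).

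Camera did not call the lists of other markers of tissues that can adhere to a dissected brain. Of 21 head fat body markers 3 rose, 1 fell and 17 did not pass, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.0666), with the gluconeogenic enzyme Pepck1 at 1.42 ± 0.32 (adjusted p = 0.012). Of 14 haemocyte markers 1 rose, 4 fell and 9 did not pass, or 3 and 5 adjusted over the list alone, with the collagen vkg at -1.11 ± 0.24 (adjusted p = 0.00967). The haemocyte list (camera adjusted p = 0.558) had a median of 0.05, a mean of -0.13 and a test directed down, and its median was -0.10 with quantile normalization. Of 14 sex-biased transcripts 1 rose and 13 did not pass, whereas limma passed 0 when adjusted over the list alone, with 4 higher at an unadjusted p under 0.05 (camera adjusted p = 0.26, called up by fry with adjusted p = 0.0326). For the 5 gut enzyme markers limma passed 0, also at an unadjusted p under 0.05 (camera adjusted p = 0.302, and not called by fry), and the member with the smallest p, Jon66Ci, was at 0.26 ± 0.18 (adjusted p = 0.319).

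Camera did not call the remaining lists between 3d and 60d, whereas fry called DNA damage and apoptosis genes up and autophagy genes down (adjusted p = 0.00589 and 0.0326). Of 14 insulin and TOR signalling genes 2 rose, 2 fell and 10 did not pass, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.948). Of 21 autophagy genes 1 fell, also adjusted over the list alone (camera adjusted p = 0.123), and of 12 circadian clock genes 1 rose, or 2 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.253). Of 40 cytoplasmic ribosomal proteins 3 rose, with 0 passing in limma when adjusted over the list alone and 6 higher at an unadjusted p under 0.05 (camera adjusted p = 0.173, and not called by fry). Of 23 DNA damage and apoptosis genes 4 rose and 4 fell, or 6 and 5 adjusted over the list alone (camera adjusted p = 0.25), with Irbp, a DNA repair protein, at 0.66 ± 0.13 (adjusted p = 0.00833). For the 23 ecdysone response genes limma passed 0, also adjusted over the list alone, with 2 higher and 2 lower at an unadjusted p under 0.05 (camera adjusted p = 0.777, and not called by fry). The member with the smallest p was Eip63E at -0.32 ± 0.12 (adjusted p = 0.078). Of 12 mitotic cell cycle genes 2 rose, also adjusted over the list alone (camera adjusted p = 0.0596), and of 31 proteasome genes 1 rose, also adjusted over the list alone (camera adjusted p = 0.681). Of 15 small RNA pathway genes 2 fell, or 1 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.498). The medians of the insulin and proteasome lists changed sign with the scaling of the arrays.

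In the 60d against 3d comparison 1511 of 8171 genes (18.5%) passed, 656 up and 855 down, and 219 of them changed at least 2-fold (135 up and 84 down). With quantile normalization 448 rose and 980 fell, which is 31.4% up against 43.4%. With no filter 643 rose and 653 fell (49.6% up), and without 60d replicate 1 1321 rose and 1171 fell (53% up). The count was 689 without 3d replicate 3, and 2492, 941 and 606 without 60d replicates 1, 2 and 3. It was 4177 with the first arrays of 3d and 60d left out together. The fit pooled the variance of all ages, whose median within-age SD was 0.229 at 3d, 0.094 at 30d and 0.209 at 60d. The calls for 60d against 3d thus borrowed precision from the tighter 30d arrays, which are not in the comparison. With only the 6 arrays of 3d and 60d, 540 genes passed, 227 up and 313 down. That fit also has fewer residual degrees of freedom, so the part due to unequal spread was not separated. With an estimated correlation camera called 0 lists in this comparison, with 6 at an unadjusted p under 0.05, whereas fry called 16 and the preset correlation 14.

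**Figure D2:**
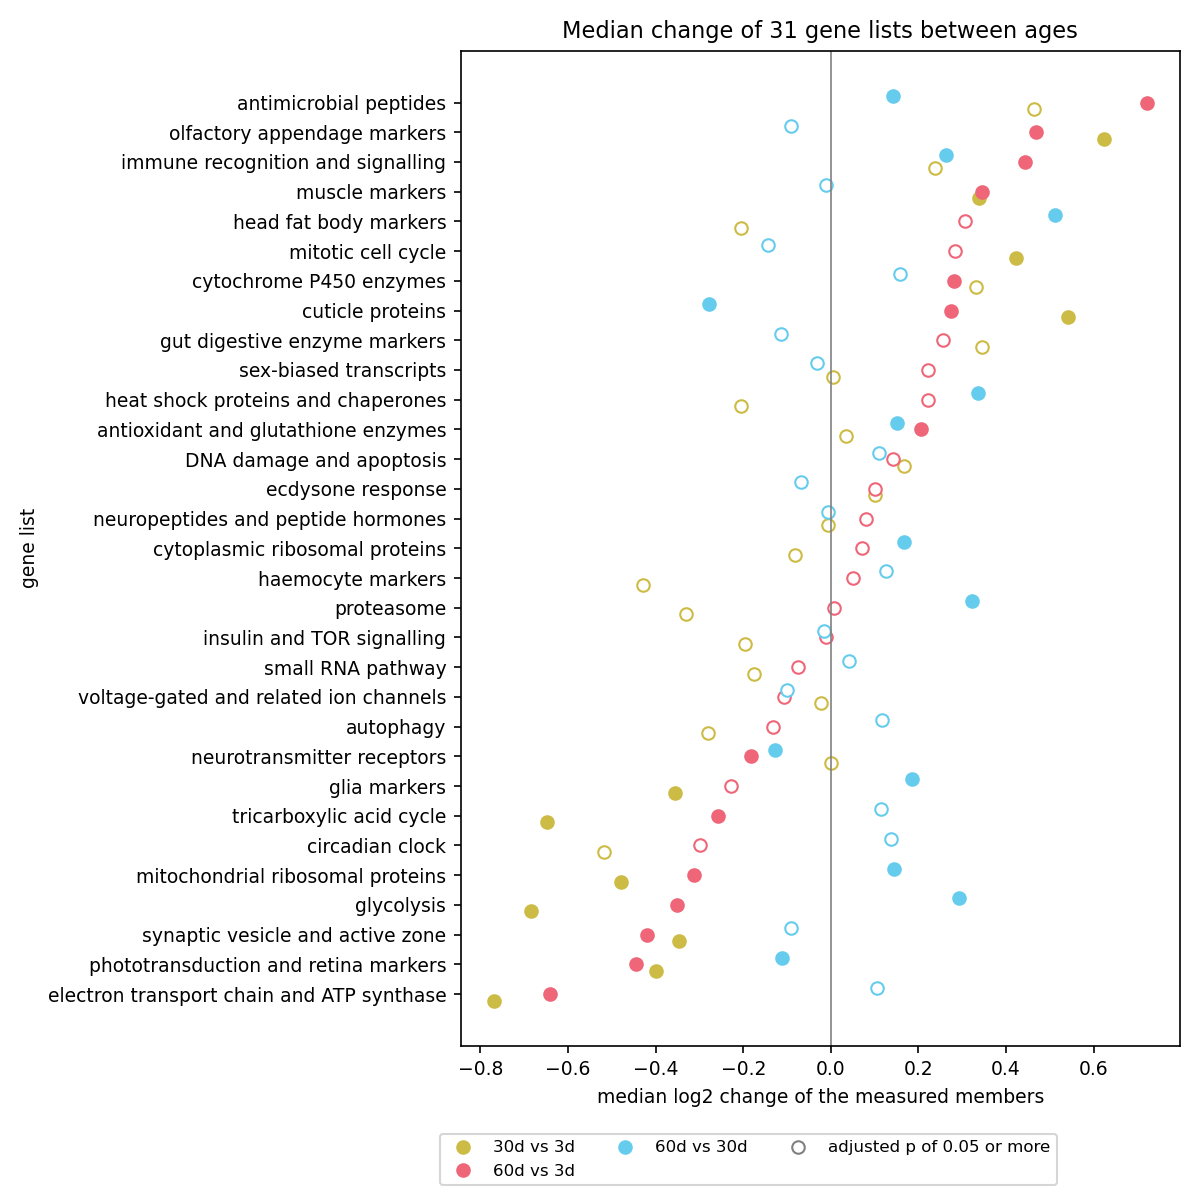
Median log2 change of the measured members of each of 31 gene lists on the horizontal axis, with 1 point per list for each of 3 comparisons. Filled points have a camera adjusted p below 0.05 at the preset correlation of 0.01 and open points do not. The electron transport list lies at -0.77 in 30d against 3d and at -0.64 in 60d against 3d.

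Many energy metabolism transcripts were lower at 30d than at 3d. Of the 67 electron transport and ATP synthase genes 51 fell, 4 rose and 12 did not pass, or 54 and 6 adjusted over the list alone (camera adjusted p = 3.71e-11). ND-75 was at 7.44 ± 0.09 at 30d, a change of -1.42 ± 0.24 from 3d, and ATPsyngamma fell by 1.36 ± 0.18 (adjusted p = 0.00286 and 0.00203). Of the 11 tricarboxylic acid cycle genes 7 fell and 4 did not pass, or 9 fell adjusted over the list alone (camera adjusted p = 0.00226), including mAcon1 at -1.14 ± 0.16 and muc, a subunit of pyruvate dehydrogenase, at -1.10 ± 0.14 (adjusted p = 0.00234 and 0.00176). Of the 69 mitochondrial ribosomal proteins 34 fell and 35 did not pass, or 40 fell adjusted over the list alone (camera adjusted p = 1.35e-08), including mRpS9 at -0.99 ± 0.18 (adjusted p = 0.00392). Of the 10 glycolysis genes 7 fell and 3 did not pass, as also adjusted over the list alone (camera adjusted p = 0.00615), including Pgk at -1.45 ± 0.20 and Gapdh1 at -1.26 ± 0.19 (adjusted p = 0.00203 and 0.0024). With quantile normalization the glycolysis list was not called (adjusted p = 0.0802). Each of these lists had adjusted p = 0.493 with an estimated correlation.

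Other large changes by 30 days involved eye, redox and clock genes. Tsp42Ed rose by 1.74 ± 0.18 and TotC by 1.42 ± 0.29, while wun2, retinin and e fell by 1.91 ± 0.16, 1.91 ± 0.18 and 1.76 ± 0.20 (adjusted p = 0.00123, 0.00512, 0.000428, 0.000565 and 0.00159). The oxidoreductase family gene CG9512 fell from 10.58 ± 0.10 to 7.87 ± 0.32, 6.56-fold (adjusted p = 0.000205). Of the 44 antioxidant and glutathione genes 11 rose, 7 fell and 26 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.62). The catalase Cat fell by 1.57 ± 0.27 and Sod2 by 1.14 ± 0.14, while GstD4 rose by 0.85 ± 0.19 (adjusted p = 0.00318, 0.00176 and 0.00809). Of the 12 clock genes 2 rose, 5 fell and 5 did not pass, as also adjusted over the list alone (camera adjusted p = 0.269, called down by fry with adjusted p = 0.0436). The activator Clk rose by 0.82 ± 0.15, and the repressor per and the light sensor cry fell by 1.13 ± 0.26 and 0.98 ± 0.21 (adjusted p = 0.00379, 0.00806 and 0.00685). No hour of collection entered the comparison, so for clock genes a difference in time of day cannot be told apart from age. Of the 9 antimicrobial peptide genes 3 rose and 6 did not pass, or 1 rose adjusted over the list alone (camera adjusted p = 0.0579), and of the 34 immune recognition genes 13 rose, 3 fell and 18 did not pass, as also adjusted over the list alone (camera adjusted p = 0.0914, called up by fry with adjusted p = 0.0301). The median of the immune recognition list was 0.24 and changed sign with quantile normalization, at -0.04.

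Between 3d and 30d camera called cuticle, cell cycle, muscle and olfactory lists up and eye, synaptic and glial lists down. Of the 48 cuticle proteins 24 rose, 1 fell and 23 did not pass, or 30 and 1 adjusted over the list alone (camera adjusted p = 1.32e-06), among them Cpr72Ec at 1.42 ± 0.32 and TwdlZ at 0.97 ± 0.20 (adjusted p = 0.00785 and 0.00604). Of the 12 mitotic genes 4 rose and 8 did not pass, as also adjusted over the list alone (camera adjusted p = 0.0136), among them the neural precursor factor ase at 0.97 ± 0.16 and the cyclin CycB3 at 0.84 ± 0.18 (adjusted p = 0.00286 and 0.0064). Of the 20 muscle markers 8 rose, 1 fell and 11 did not pass, as also adjusted over the list alone (camera adjusted p = 0.0199), with Mf at 0.70 ± 0.14 (adjusted p = 0.00511), and the call was lost without 3d replicate 2 (adjusted p = 0.0638) and with no filter (adjusted p = 0.235). Of the 7 olfactory appendage markers 6 rose, as also adjusted over the list alone (camera adjusted p = 0.0112), with Obp19d at 1.07 ± 0.23 (adjusted p = 0.00697). Of the 27 retina genes 14 fell, 1 rose and 12 did not pass, as also adjusted over the list alone (camera adjusted p = 0.0112), with boss at -1.05 ± 0.14 (adjusted p = 0.00203). Of the 28 synaptic genes 10 fell and 18 did not pass, as also adjusted over the list alone (camera adjusted p = 0.00785), with Rop at -1.14 ± 0.20 and the clathrin adaptor AP-2alpha at -0.87 ± 0.14 (adjusted p = 0.00325 and 0.00256). Of the 21 glia markers 7 fell, 1 rose and 13 did not pass, as also adjusted over the list alone (camera adjusted p = 0.0151). With quantile normalization the olfactory, retina, synaptic and glial lists were not called (adjusted p = 0.128, 0.136, 0.349 and 0.208), and with cyclic loess the retina, synaptic and glial lists were not (adjusted p = 0.104, 0.191 and 0.191). The stricter filter also ended the glial call (adjusted p = 0.0699). Against random lists of the same signal levels, the medians of the mitotic (0.42) and glial (-0.36) lists lay within the middle 95% (-0.33 to 0.50 and -0.40 to 0.08). Each list of this group had adjusted p = 0.493 with an estimated correlation.

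Camera did not call the other lists between 3d and 30d, although several held genes that changed, and fry called receptors and haemocyte markers down (adjusted p = 0.0113 and 0.0462). Of the 28 heat shock proteins and chaperones 4 rose and 10 fell, or 4 and 11 adjusted over the list alone (camera adjusted p = 0.244), and the mitochondrial chaperones Trap1 and Hsp60A fell by 0.98 ± 0.16 and 0.96 ± 0.17 (adjusted p = 0.00286 and 0.00341). Of the 14 insulin and TOR genes 3 rose and 3 fell, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.781), with the transcription factor foxo at 0.59 ± 0.13 and Ilp5 at -1.26 ± 0.22 (adjusted p = 0.00726 and 0.00331). Of the 31 neuropeptides 5 rose and 6 fell, as also adjusted over the list alone (camera adjusted p = 0.665), with SIFa at -1.19 ± 0.15 (adjusted p = 0.00176). Of the 29 receptors 2 rose and 10 fell, as also adjusted over the list alone (camera adjusted p = 0.337), with the muscarinic receptor mAChR-B at -0.72 ± 0.13 (adjusted p = 0.00343). Of the 23 ion channels 6 fell, or 3 adjusted over the list alone (camera adjusted p = 0.492), with Irk2 at -0.72 ± 0.13 (adjusted p = 0.00382). Of the 45 P450 genes 14 rose and 6 fell, or 15 and 6 adjusted over the list alone (camera adjusted p = 0.337), with Cyp309a2 at 1.04 ± 0.20 and Cyp6d5 at -1.27 ± 0.25 (adjusted p = 0.00424 and 0.00483). Of the 14 haemocyte markers 2 rose and 5 fell, as also adjusted over the list alone (camera adjusted p = 0.14), with vkg at -1.66 ± 0.24 (adjusted p = 0.00228). Of the 15 small RNA genes 3 rose and 5 fell, as also adjusted over the list alone (camera adjusted p = 0.588), with AGO3 at 0.93 ± 0.17 (adjusted p = 0.00328).

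The lists left were not called by camera at 30d, whereas fry called autophagy genes down and sex-biased transcripts and gut markers up (adjusted p = 0.0113, 0.0398 and 0.0462). Adjusted over all genes, 3 head fat body markers rose and 2 fell of 21 (2 and 2 adjusted over the list alone, camera adjusted p = 0.588), 2 proteasome genes rose and 7 fell of 31 (1 and 6, camera adjusted p = 0.0549), and 6 autophagy genes fell of 21 (3, camera adjusted p = 0.0914). Among DNA damage and apoptosis genes 7 rose and 6 fell of 23 (the same adjusted over the list alone, camera adjusted p = 0.556), and among ecdysone response genes 4 rose and 4 fell of 23 (the same, camera adjusted p = 0.371). Cytoplasmic ribosomal proteins had 3 that rose and 1 that fell of 40 (camera adjusted p = 0.665), and adjusted over the list alone limma passed 0, with 6 higher and 4 lower at an unadjusted p under 0.05 (not called by fry). Of 14 sex-biased transcripts 4 rose, or 3 adjusted over the list alone (camera adjusted p = 0.364), among them the male accessory gland transcripts Acp26Aa and Acp62F at 1.01 ± 0.17 and 0.92 ± 0.19 (adjusted p = 0.00306 and 0.00606). Of 5 gut enzyme markers 1 rose, also adjusted over the list alone (camera adjusted p = 0.201). The medians of the antioxidant, cytoplasmic ribosomal, DNA damage, neuropeptide and ion channel lists changed sign with the scaling of the arrays, and that of the receptor list was 0.00 as deposited and 0.08 with quantile normalization.

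In the 30d against 3d comparison 3455 of 8171 genes (42.3%) passed, 1714 up and 1741 down, and 262 changed at least 2-fold (103 up and 159 down). With quantile normalization 1182 rose and 2131 fell, which is 35.7% up against 49.6%. The balance leaned the other way with no filter, at 2430 up and 1613 down (60.1% up). It also did with every probe set as its own unit, at 3475 up and 1975 down (63.8% up). Direction went with signal level, since of 3 equal bins of genes by signal the dimmest held 874 genes that rose and 358 that fell, and the brightest 276 and 769. The count was 1555 without 3d replicate 3, and 2108, 1732 and 1668 without 30d replicates 1, 2 and 3, and 5389 with the first arrays of 3d and 60d left out together. With an estimated correlation camera called 0 lists, with 1 at an unadjusted p under 0.05, whereas fry called 18 and the preset correlation 11.

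Between 30 and 60 days a small set of transcripts rose, among them immune, stress and detoxification genes. TotC rose from 6.87 ± 0.16 to 11.22 ± 0.31, 20.3-fold (adjusted p = 4.52e-05), and Diedel, Spn88Eb and Cyp6g1 rose by 2.46 ± 0.32, 1.98 ± 0.22 and 2.00 ± 0.23 (adjusted p = 0.00667, 0.00407 and 0.00407). Drs rose by 1.23 ± 0.19 (adjusted p = 0.0154), although this call was lost without 30d replicate 1 or 2 (adjusted p = 0.0615 and 0.0831) and without 60d replicate 1 or 3 (adjusted p = 0.0715 and 0.0687). The muscle LIM protein Mlp60A rose by 1.47 ± 0.20 (adjusted p = 0.00823), a call lost without 30d replicate 1 (adjusted p = 0.0615). The peptidase-like gene Nepl21 rose by 2.79 ± 0.40 (adjusted p = 0.00935), a call lost without 30d replicate 1 or 3 or 60d replicate 3 (adjusted p = 0.0615, 0.0545 and 0.0544). In all 44 of 8171 genes passed, 43 up and 1 down, and 1235 had an unadjusted p under 0.05. The fall was that of CG31556 at -1.01 ± 0.19 (adjusted p = 0.047), which did not pass without 3d replicate 2 (adjusted p = 0.0629), without 30d replicates 1, 2 and 3 (adjusted p = 0.27, 0.152 and 0.134) or without 60d replicates 1 and 3 (adjusted p = 0.19 and 0.177). It was lost in 13 of 24 alternatives, among them no filter (adjusted p = 0.11), median centring (adjusted p = 0.0516) and cyclic loess (adjusted p = 0.0511). The count of 44 became 89 and 28 without 3d replicates 1 and 2, became 9, 17 and 18 without 30d replicates 1, 2 and 3, and became 20, 502 and 17 without 60d replicates 1, 2 and 3. Without 60d replicate 2 the direction was less one-sided, with 356 up and 146 down, and array weights, from a fit that stopped before converging, gave 2643 up and 2034 down.

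As lists, immune, chaperone and proteasome transcripts were higher at 60d than at 30d. Of the 34 immune recognition genes 2 rose, or 9 adjusted over the list alone (camera adjusted p = 5.3e-05, and adjusted p = 0.503 with an estimated correlation). Of the 28 heat shock proteins and chaperones 1 rose, or 11 adjusted over the list alone (camera adjusted p = 2.09e-06), and of the 9 antimicrobial peptides 1 rose, or 3 adjusted over the list alone (camera adjusted p = 0.0198). The median antimicrobial peptide, at 0.14, lay within the middle 95% of random lists of the same signal levels (-0.24 to 0.23). For the 31 proteasome genes limma passed 0, also adjusted over the list alone, with 11 higher at an unadjusted p under 0.05 (camera adjusted p = 5.3e-05). Of the 21 head fat body markers limma passed 0, with 8 that rose adjusted over the list alone and 9 higher at an unadjusted p under 0.05 (camera adjusted p = 0.000954). The fat body marker with the smallest p, fat-spondin, was at 0.98 ± 0.25 (adjusted p = 0.126). Of the 44 antioxidant genes 1 rose, or 4 adjusted over the list alone (camera adjusted p = 0.0149). Glia markers, glycolysis, cytoplasmic ribosomal and mitochondrial ribosomal proteins were also called up (camera adjusted p = 0.0149, 0.0174, 0.0149 and 0.0149). In these lists limma passed 0 members, with 5, 1, 8 and 3 higher at an unadjusted p under 0.05, and adjusted over the list alone 3 glia markers rose. Called down were cuticle proteins, phototransduction and retina genes, and neurotransmitter receptors (camera adjusted p = 2.09e-06, 0.0149 and 0.0354), where limma passed 0 members and 5, 5 and 1 were lower at an unadjusted p under 0.05. Adjusted over the list alone 1 cuticle protein and 1 retina gene fell. Relative to the 3d mean, the median cuticle gene stood at 0.50, 0.56 and 0.55 on 30d replicates 1, 2 and 3 and at -0.06, 0.50 and 0.35 on those of 60d, and the median proteasome gene at -0.28, -0.33 and -0.31 and at 0.30, -0.21 and 0.06. On 60d replicate 2 both thus lay near their 30d levels, and they lay farthest from them on 60d replicate 1, although both calls held without that array. The cuticle protein Cpr72Ec was at -1.60 ± 0.32 (adjusted p = 0.0579). With an estimated correlation the called lists other than the immune one had adjusted p = 0.514 (10 lists), 0.574 (cytoplasmic ribosomal) or 0.661 (mitochondrial ribosomal).

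The list calls between 30d and 60d depended on the test, on single arrays, on scaling and on the filter. With an estimated correlation camera called 0 of 31 lists, with 1 at an unadjusted p under 0.05, and fry called 1, immune recognition and signalling, whereas the preset correlation called 13. Without 60d replicate 2 the count of 13 lists fell to 8, with calls lost for antimicrobial peptides (adjusted p = 0.275), antioxidant enzymes (adjusted p = 0.0505), cytoplasmic ribosomal proteins (adjusted p = 0.0547), receptors (adjusted p = 0.0718) and retina genes (adjusted p = 0.127). Without 60d replicate 1 the cytoplasmic ribosomal, glial, glycolysis and mitochondrial ribosomal calls were lost (adjusted p = 0.122, 0.0664, 0.131 and 0.216), and without 60d replicate 3 that of the receptors (adjusted p = 0.0651). Without 30d replicate 1 the antimicrobial and receptor calls were lost (adjusted p = 0.0637 and 0.103), without 30d replicate 2 those of both ribosomal lists (adjusted p = 0.094 and 0.0822), and without 30d replicate 3 the glial one (adjusted p = 0.0631). With the first arrays of 3d and 60d left out together the cytoplasmic ribosomal, glial, glycolysis and mitochondrial ribosomal lists were not called (adjusted p = 0.136, 0.143, 0.156 and 0.134). The glial call was also lost with quantile normalization (adjusted p = 0.0764), the mitochondrial ribosomal one with the stricter filter (adjusted p = 0.0663), those of antimicrobial peptides, receptors and retina genes with no filter (adjusted p = 0.17, 0.204 and 0.103), and that of antimicrobial peptides with camera on ranks (adjusted p = 0.0911).

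The lists not called between 30d and 60d had few members that passed. Adjusted over all genes 3 muscle markers, 1 P450 gene and 1 haemocyte marker rose, and adjusted over the list alone 3, 7 and 1 rose (camera adjusted p = 0.491, 0.0525 and 0.0525), with 1 P450 gene falling. Of 7 olfactory appendage markers 2 rose and 1 fell adjusted over the list alone, and 0 passed over all genes. Limma passed 0 members of the electron transport (camera adjusted p = 0.211), tricarboxylic acid cycle (0.185), autophagy (0.419), clock (0.575), DNA damage (0.344), ecdysone (0.212), gut (0.311), insulin (0.846) and mitotic (0.0838) lists. The same held for the neuropeptide (0.846), olfactory (0.803), sex-biased (0.689), small RNA (0.846), synaptic (0.0521) and ion channel (0.129) lists. At an unadjusted p under 0.05 the electron transport list had 1 member higher and 1 lower, and the synaptic list 1 lower. Median, mean and test differed in sign for the insulin, muscle, neuropeptide, olfactory, sex-biased and small RNA lists. The sex-biased fat body transcript fit was at 1.22 ± 0.51 (adjusted p = 0.299).

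Most genes called at 60d against 3d were also called at 30d against 3d, though not with a 2-fold minimum in both. Of the 1511 genes called at 60d against 3d, 1254 were also called at 30d against 3d in the same direction, 444 up and 810 down, and 1 was called in the opposite direction. Independent calls would give 137.6 up and 182.2 down. With a 2-fold minimum in both comparisons the overlap was 93 of 219 genes. Across genes, which are not independent replicates, the log2 changes of these comparisons had a correlation of 0.792 against 0.501 in simulated unchanged groups sharing the 3d arrays, and the shared 3d arrays add to the overlap. The simulation gave all ages the same SD, whereas the median SD was 0.229, 0.094 and 0.209 at 3d, 30d and 60d. With 3d arrays more spread than those of 30d, unchanged groups could correlate more than 0.501, so the size of the gap is not known. Catalase is an example of a gene whose change differed between the intervals: Cat was at 8.83 ± 0.18, 7.27 ± 0.20 and 8.02 ± 0.67 at 3d, 30d and 60d. The change from 30 to 60 days minus that from 3 to 30 days was 2.31 ± 0.47 for Cat (adjusted p = 0.0307) and 2.93 ± 0.49 for TotC (adjusted p = 0.0307). Both calls were lost without 3d replicate 3 (adjusted p = 0.0687), without 30d replicates 1, 2 and 3 (adjusted p = 0.121, 0.133 and 0.141), without 60d replicate 3 (adjusted p = 0.0613) and with no filter (adjusted p = 0.0564).

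This difference between intervals passed for 1507 genes, 829 positive and 678 negative, and with quantile normalization for 1287 positive and 504 negative, which is 71.9% against 55% positive. With every probe set as its own unit the balance turned, at 918 positive and 1460 negative (38.6% positive). The count of 1507 became 3465 and 1 without 3d replicates 1 and 3, and 688, 3149 and 1 without 60d replicates 1, 2 and 3. Without 30d replicates 1 and 3 it was 1 each, and without 30d replicate 2 limma called 0, with 2234 at an unadjusted p under 0.05. Over all 3 ages the limma F-test passed 2779 genes (34%), which became 992 without 3d replicate 3, 1355, 1227 and 1235 without 30d replicates 1, 2 and 3, and 1770 without 60d replicate 3.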

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

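The tests of sample splits, of signal level within the electron transport list and of that list without 3d replicate 1 were set before their results were seen. Those of the 30d against 3d count, of the share of neurons and of fat body and haemocytes were chosen only after the result was seen, and how the neuron, fat body and haemocyte values were read was revised after they were known.

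For 1507 genes the change from 30 to 60 days differed from that from 3 to 30 days, by limma's test of the difference itself. The largest positive differences were in Lsp2, a larval storage protein, at 3.59, CG9512 at 3.52, Nepl21 at 3.27, TotC at 2.93, CG10560 at 2.71 and Cat at 2.31 (log2). The largest negative differences were in Cpr72Ec at -3.02, CG33109 at -2.21, CG13198 at -1.75, the gustatory receptor Gr39b at -1.67, the glue protein gene Sgs4 at -1.66 and Obp47b at -1.65. The calls of these 12 genes were lost without 30d replicate 2 (adjusted p = 0.0517 for CG9512 and 0.133 to 0.14 for the others). Those other than CG9512 were also lost without 3d replicate 3 (adjusted p = 0.0687 to 0.0785), 30d replicate 1 (0.121 to 0.151), 30d replicate 3 (0.141 to 0.172) and 60d replicate 3 (0.0613 to 0.0905). Lsp2, CG33109 and Obp47b were lost without 60d replicate 1 as well (adjusted p = 0.0821, 0.0521 and 0.0518). With no filter those other than CG9512 were lost too (adjusted p = 0.0564 to 0.0719). Lsp2 was lost in 12 of 23 alternatives, among them median centring (adjusted p = 0.0517), the floor (0.0552), the prior with trend (0.0631), the replicate block (0.0566) and cyclic loess (0.063). In splits of the 9 arrays, 1 of 100 gave as many genes as the real one, namely the real one itself, with 1172 as the highest other. Such splits mix all the ages, though some keep part of the grouping by age, so they do not test whether the intervals differ. Chance is not excluded for this count. For the F-test over the 3 ages, where no effect of age is what is tested, the same share was 1 of 100, with 2779 genes against 2034 in the highest other split. That other split kept the 3 arrays of 3d together, so it still held part of the grouping by age. That share is the smallest that 100 splits can give, so chance is unlikely there but not excluded.

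Probe sets outside the gene comparisons were also called between ages. Of 2967 tested probe sets with no gene named, 273 were called between 60d and 3d (205 up and 68 down), 1584 between 30d and 3d (1433 up and 151 down) and 8 between 60d and 30d (all up). Of 277 tested probe sets with several genes named, 35, 120 and 2 were called in these comparisons. Among the unnamed probe sets rises far outnumbered falls between 3d and 30d, whereas 1714 genes rose and 1741 fell. In that comparison the dimmest genes had a median change of 0.275, and of 0.068 after cyclic loess. The unnamed probe sets were not counted after other scalings, so a difference that depends on signal level cannot be told apart from age.

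More genes were called between 3d and 30d (3455) than in either comparison with 60d. Without 3d replicate 1, the array with low 5' control signal, the count was 4559, against 2057 for 60d against 3d and 89 for 60d against 30d. Each count rose, so the rise does not show what drives the excess, but the excess did not need that array. Without 3d replicate 3 the counts were 1555, 689 and 33. After cyclic loess between arrays the 30d against 3d count was 3080, which argues against a difference that depends on signal level as the whole cause. On the axis from the mean 3d array to the mean 30d array, 60d replicates 1, 2 and 3 lay at 0.35, 0.99 and 0.71, a span of 0.64. The 3d arrays lay at 0.33, 0.28 and -0.21, each on an axis drawn without the array itself. Their positions thus cannot be set directly against those of 60d. A component that moves many genes together and also varies between arrays of the same age may therefore add to the spread at 3d and 60d, although this test was worded after the positions had been seen. The median signal of 60d replicates 1, 2 and 3 was 66.5, 77.0 and 74.3, in the same order as their positions on the axis. With median centring 3443 genes passed for 30d against 3d. Age itself, a batch the labels do not give and differences in dissection stay open and were not tested.

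The median electron transport and ATP synthase gene was at -0.64 in 60d against 3d. It lay at percentile 0 of 10000 random lists of the same signal levels, whose middle 95% ran from -0.18 to 0.05, which argues against a dependence on signal level, and at -0.70 without 3d replicate 1, which argues against the low 5' signal of that array. A lower share of neurons could lower both this list and the synaptic list, since their mean changes differed by -0.12 (95% interval -0.28 to 0.04), and this stays open. Over bright members, the list's mean was -0.57 (63 genes) and that of 4 neuronal lists -0.23 (96 genes), a difference of -0.34 (95% interval -0.46 to -0.21). Means of the 4 lists ran from -0.41 (synaptic) to -0.04 (neuropeptides). Both intervals resample genes, which vary together, and leave out the spread between arrays. Among these lists the electron transport median was lowest on each 60d array, at -0.43 against -0.32 for synaptic genes on replicate 1. A loss of neurons of every kind as the whole cause thus looks less likely but stays open. A loss of particular neurons or of synaptic transcripts, and a change within cells with age, remain open.

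Among 34 immune recognition and 9 antimicrobial peptide genes 16 rose between 3d and 60d, and the medians over all members were 0.44 (0.28 with quantile normalization) and 0.72. More fat body carried along with old brains is a candidate source: its 6 brightest markers had a median change of 0.17 (95% interval -0.39 to 0.54), with Yp1 at 0.17, Obp44a at -0.64, apolpp at 0.31, Lsd-2 at 0.17, Tsf1 at 0.76 and FASN1 at -0.14. For haemocytes the median was -0.15 (95% interval -1.26 to 0.34), with Col4a1 at -0.48, crq at 0.19, vkg at -1.11, lz at 0.36, He at 0.32 and Pxn at -1.41. All 12 were bright in 3d brains already and would hide a small added share, so neither tissue can be told apart from a rise within the brain. The whole fat body list lay at 0.31, percentile 99.9 of random lists, though its median was -0.31 on 60d replicate 2, where the median immune recognition gene was at 0.42.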

How the results depend on the processing

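The first arrays of 3d and 60d left out together, cyclic loess, the 3' to 5' ratio as a covariate and, for lists, the pseudocount of 16 were chosen after seeing the data. Quantile normalization gave 1428, 3313 and 81 genes for 60d against 3d, 30d against 3d and 60d against 30d. Where a value moved by over 1.5 times and nothing else is said, the cause was not tested.

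Array weights gave 4664, 5534, 4677 and 5676 genes (the last for the difference between intervals) and 6810 by the F-test, from a weight fit that stopped before converging. Without the first arrays of 3d and 60d the counts were 4177, 5389, 74, 3652 and 5123. A 2-fold minimum, a stricter threshold by construction, left 219 genes for 60d against 3d, 262 for 30d against 3d and 413 by the F-test, and an overlap of 93. With only the 6 arrays of 3d and 60d, 540 genes passed. With every probe set as its own unit, which tests more of them, 5450 passed for 30d against 3d and 2378 for the difference between intervals. With no filter 22 genes passed for 60d against 30d and 2 for the difference between intervals. Cyclic loess gave 24 for 60d against 30d, the 3' to 5' covariate 68 there and 3305 for the difference between intervals. Replicate numbers did not pair the arrays (correlations of residuals between same-number pairs -0.33 to 0.14), and a replicate block gave 1239, 3031, 20 and 948.

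Leaving out each array gave 606 to 2492 genes for 60d against 3d, 1555 to 4559 for 30d against 3d, 9 to 502 for 60d against 30d, 0 to 3465 for the difference between intervals and 992 to 3956 by the F-test. The 0 came from limma without 30d replicate 2, with 2234 genes at an unadjusted p under 0.05. For gene lists it gave 8 to 15 between 30d and 60d. Camera with an estimated correlation called 0 lists in each comparison (6, 1 and 1 at an unadjusted p under 0.05), fry 16, 18 and 1, and quantile normalization 6 for 30d against 3d. The spread at 30d was 0.085 with the stricter filter.

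Of 2881 alternative values for named genes between 3d and 60d, 2502 kept direction and side of the threshold, 359 lost their call, 15 gained one and 5 changed sign. For 30d against 3d the numbers were 2286, 208 and 0 of 2495, with 1 change of sign, the cell death ligand egr at -0.04 with the mean of its probe sets. For 60d against 30d, 375 of 478 were kept, 89 lost and 14 gained, and for the difference between intervals 200 of 275 were kept and 75 lost. The 5 changes of sign were in fat body markers that did not pass the test. Yp1 ranged from -0.03 to 0.43 as each array was left out, and FASN1 from -0.36 to 0.07, with 0.01 after cyclic loess and 0.05 with the 3' to 5' covariate. Signals near background limit what the arrays can show of dim genes.

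The 6 arrays of a comparison can be split into groups of 3 in 10 ways, the real one included, too few for a share under 0.05. The real split called 1511, 3455 and 44 genes and the highest other called 0 in each comparison by limma, with up to 2410, 661 and 619 at an unadjusted p under 0.05, so 1 split gave as many. For lists the real splits called 14, 11 and 13 and the highest others 15, 10 and 10, so that 2, 1 and 1 of 10 gave as many and camera at its preset correlation calls lists in such splits too.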

Other observations

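The genes in this part come from the rule for named genes, and no test here was chosen only after its result was seen. Some transcripts with no place in the lists rose over both intervals. Tsp42Ed went from 6.36 ± 0.25 at 3d through 8.10 ± 0.16 at 30d to 9.63 ± 0.29 at 60d, and CG9150 from 4.78 ± 0.10 through 6.26 ± 0.11 to 7.52 ± 0.34 (log2 mean ± SD, n = 3 arrays each). Both passed in all 3 pairwise comparisons, with adjusted p = 0.00123 and 0.00176 for the first interval and adjusted p = 0.0044 and 0.00673 for the second. The second call of CG9150 was lost without 30d replicate 1 (adjusted p = 0.0615), and its 3d mean lay below the filter value of 5.71.

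Other genes had their low level by 30 days: wun2 stood at 7.87 ± 0.22, 5.96 ± 0.06 and 5.87 ± 0.26 at 3d, 30d and 60d. Retinin stood at 7.05 ± 0.21, 5.15 ± 0.12 and 5.20 ± 0.30, with the means at 30d and 60d below the filter value of 5.71. The clathrin adaptor subunit AP-2mu was at -1.54 ± 0.15 in 60d against 3d (adjusted p = 0.000312). Uncharacterised genes with falls between 3d and 60d included CG5644 at -1.64 ± 0.15, CG17005 at -1.57 ± 0.19 and CG9394 at -1.54 ± 0.19 (adjusted p = 0.000188, 0.00064 and 0.00064).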
